A study of Mus musculus with 24 samples.

How the data were processed

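Chromatin immunoprecipitation with an antibody against H3K27Ac, histone H3 acetylated at lysine 27 and a mark of active promoters and enhancers, was followed by sequencing in mouse brain, heart, kidney and liver. Each organ was either flash frozen (Frozen) or fixed in formalin and embedded in paraffin (FFPE). Per the labels' protocols, Frozen tissue cores were crosslinked in 1% formaldehyde for 30 min, FFPE tissue had been fixed in 10% formalin and its chromatin was extracted at 95 °C for 20 min, and chromatin of both kinds was sheared by ultrasound in a PIXUL instrument. The labels describe 24 samples, of which 16 are H3K27Ac libraries, 2 in each of the 8 combinations of organ and preservation, and 8 are inputs, chromatin sequenced without immunoprecipitation.

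Per the submitters' processing notes, Bowtie2, featureCounts and limma were used with the mouse build mm10. Their versions, the part of each gene over which reads were counted and the handling of reads with several positions are not given in the sources used here. The deposited table holds 27179 genes with Entrez identifiers and 8 columns of log2 values, 1 for each organ and preservation. The columns carry no replicate number, and no input column was analysed here. Whether a column is 1 replicate or merged reads is not given in the sources used here. The 8 columns were therefore taken as 8 libraries, 1 per group. The labels also name 2 ChIP runs, replicate 1 in one and replicate 2 with the inputs in the other, and 2 alternative library kits. Neither can be matched to the columns, so any comparison could mix runs or kits.

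The unit of the deposited values was worked out from the values themselves. In each column 100% of the values returned a whole count, within 0.001, as log2 of the count plus 0.5, scaled to an effective library size. The values are thus log2 CPM, reads per gene relative to the library size on a log scale, after a scaling by the authors, with factors between 0.749 and 1.22 relative to the total count. Total counts were 4404789 to 6164562 per library, and the median gene had 87 to 119 counts. These counts were used to state depth and counting error, and every test was made on the deposited log2 values. Genes at 0 counts in all libraries, 235 in number, were removed and 26944 were tested. A symbol was missing in 1275 of the table's rows. Of the identifiers, 25275 matched a RefSeq gene table of assembly GRCm38, the assembly of mm10, from which positions are given. Across 25102 genes, which are not independent replicates, the value of a gene and its genomic span had Spearman correlations between 0.468 and 0.611, so values are compared between libraries for 1 gene and not between genes.

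The tests fixed before the data were examined assumed 2 replicate columns per group. With 1 column per group, the test of preservation within each organ, the test of organs within each preservation, the test of preservation effects that differ between organs and the tests against input were not made. Two-sided tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a prior variance that follows the mean value), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. FFPE was compared with Frozen over the 4 organs in a model with organ and preservation, which leaves 3 residual degrees of freedom and takes the organs as replicates. The comparison of each organ with the other 3 over both preservations used the same model and was chosen after the columns had been seen. The labels do not say which columns came from the same animal, and p-values measure the spread among these 8 libraries after the additive effects are removed.

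Values within 1 organ or 1 preservation are given without a p-value. Counts of genes with at least a 2-fold difference took genes with at least 40 counts over a pair of libraries, or 80 over the 4 libraries of a preservation, minimums that were chosen after the table had been seen. The number that counting error alone would give was simulated from binomial draws. Ratios of counts have exact Clopper-Pearson 95% intervals, and a count of 0 was taken to allow up to 3 counts. Intervals and floors cover counting error only.

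Before the data were examined, 21 gene lists were fixed, for neurons, glia, cardiomyocytes, nephron cells, hepatocytes, endothelial cells, macrophages, lymphocytes, fibroblasts and smooth muscle, adipocytes and erythroid cells, and for housekeeping, immediate early, heat shock, hypoxia, ribosomal protein, oxidative phosphorylation, clustered histone, Hox, olfactory receptor and vomeronasal receptor genes. Lists were tested with camera in limma with a preset correlation of 0.01 and again with an estimated correlation. For single libraries, the median of a list was ranked among 10000 random lists of genes matched on mean level. Named genes followed a rule fixed at the same time. It took the 5 genes with the largest rise and the 5 with the largest fall among those past the threshold whose libraries did not overlap between the sides, or had the same sign in all 4 organs. It passed over predicted genes, small RNAs, pseudogenes and identifiers without a symbol. It added up to 3 members of each list with a camera adjusted p under 0.05, and the markers Snap25, Gfap, Myh6, Nppa, Umod, Slc34a1, Alb, Apoa1, Actb and Gapdh.

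The limma step was tested on simulated data made from the 26944 genes with 200 changed, drawn only from genes above a minimum mean level. Each gene was given its fitted residual spread, capped at 1 (log2), independently of other genes, and Poisson counting error on top. Counting error, already part of the residual spread, thus entered again, and structure shared between genes was absent. The rates that follow therefore need not hold for the real data. For FFPE against Frozen it called 18 of 100 genes changed by 1 (log2), 87 of 100 changed by 2, and 4 unchanged genes. For brain against the other organs it called 9 of 100 and 74 of 100, and 3 unchanged genes. Alternatives were quantile normalization, removal of the lowest 25% of genes by mean value, a prior variance without trend and every library left out in turn. Setting all libraries to the same median and spread and leaving out the 15 mitochondrial genes were added after the data had been seen. Calculations outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.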

Results

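The table gave H3K27Ac over genes in 8 libraries, 1 for each of brain, heart, kidney and liver in each preservation, flash frozen or formalin-fixed and paraffin-embedded. Total counts ran from 4404789 in liver FFPE to 6164562 in liver Frozen. Outside mitochondrial genes they ran from 3674891 in heart FFPE to 5838402 in liver Frozen, and the liver FFPE to Frozen ratio was 0.658. Between 360 and 608 genes had 0 counts in a library. With 1 library per group no value within an organ has a replicate error. The design addresses how the H3K27Ac profile of an organ compares between FFPE tissue and frozen tissue, and how organs differ within each. The labels give neither the strain nor the animal behind a column. A difference between the mice used for FFPE and for Frozen tissue therefore cannot be told apart from preservation.

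Each organ carried H3K27Ac over the genes of its own cell types in both preservations. Neuron markers had a median of 5.88 (log2 CPM) in brain Frozen and 6.13 in brain FFPE, against 4.12 to 4.88 in the other 6 libraries. Cardiomyocyte markers stood at 6.19 in heart Frozen and 5.80 in heart FFPE, nephron markers at 6.08 in kidney Frozen and 6.03 in kidney FFPE, and hepatocyte markers at 7.14 in liver Frozen and 6.61 in liver FFPE. Across 26944 genes, which are not independent replicates, every FFPE library had its highest Pearson correlation with the Frozen library of its own organ. The same-organ values were 0.922 to 0.933 and the other-organ values 0.831 to 0.898. All 4 of 4 FFPE libraries being closest to their own organ has an exact permutation p of 0.0417, one-sided, the smallest that the 24 orders of 4 organs can give.

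**Figure D1:**
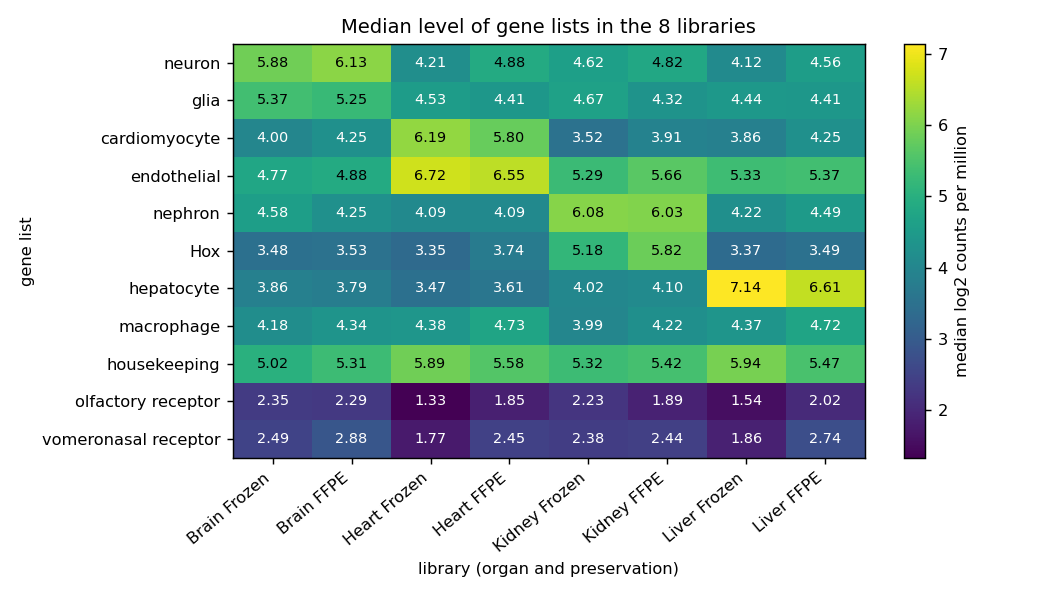
Median level of 11 gene lists, in log2 CPM, with gene lists as rows and the 8 libraries as columns. Hepatocyte genes stand at 7.14 and 6.61 in the liver libraries, and neuron genes at 5.88 and 6.13 in the brain libraries.

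Brain was set against the other organs over both preservations. Of 25 neuron markers, 22 were higher in brain and none was lower. They include Kcnc1, a potassium channel of fast-spiking neurons, by 2.50 ± 0.23 (log2, SE), the microtubule regulator Stmn2 by 2.73 ± 0.28, and the NMDA receptor subunit Grin1 by 2.20 ± 0.23. Glial genes were higher for 12 of 19 members, among them the myelin gene Mbp by 1.27 ± 0.21, and Snap25, a synaptic fusion protein, was higher by 2.18 ± 0.27. The largest differences upward were in Sncb, which encodes beta-synuclein, by 3.30 ± 0.35, Kcnk12 by 3.21 ± 0.29, Ppp2r2cos by 3.20 ± 0.35, the olfactory receptor gene Olfr1324 by 2.98 ± 0.56 and Atoh7 by 2.93 ± 0.42. The largest downward were in Zfp36, an mRNA decay factor, by -3.01 ± 0.24, Tcim by -2.89 ± 0.24, Hoxb4 by -2.70 ± 0.22, Gimap1 by -2.65 ± 0.27 and Hoxb2 by -2.61 ± 0.22.

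Several lists were lower in brain. Hepatocyte genes were lower for 16 of 26 measured members, endothelial genes for 12 of 15, with the receptor gene Kdr at -1.39 ± 0.21, and Hox genes, which pattern the body axis, for 17 of 39. The mean of the other organs includes the organ where a list is high. Hox medians, Frozen then FFPE, were 3.48 and 3.53 (log2 CPM) in brain, 3.35 and 3.74 in heart and 3.37 and 3.49 in liver. In kidney they were 5.18 and 5.82. Hepatocyte medians were 3.86 and 3.79 in brain, 3.47 and 3.61 in heart and 4.02 and 4.10 in kidney. In liver they were 7.14 and 6.61. Hox genes in brain thus lay near heart and liver, and hepatocyte genes above heart. Immediate early genes were lower for 12 of 20 members, heat shock genes for 8 of 10, ribosomal protein genes for 49 of 79 and oxidative phosphorylation genes for 34 of 78. Housekeeping genes were lower for 6 of 16 members, with a median of -0.52 (log2) and camera adjusted p = 1.69e-04, or 0.398 with an estimated correlation. The falls were thus not limited to the lists named before, and whether those lists fell further than housekeeping genes was not tested. Olfactory receptor genes had 32 of 1108 members higher and 1 lower, and adjusted over the list alone 1 was higher. The 32 are a smaller share than the 2353 of 26944 genes called higher in all. With all libraries at the same median and spread, the housekeeping median in brain was -0.45, the ribosomal protein median went from -0.74 to -0.67, the heat shock median from -1.04 to -0.79, the immediate early median from -0.94 to -0.50 and the olfactory receptor median from 0.55 to 0.14. Over the lists alone, the counts adjusted over the list alone were 22 for neuron, 14 for glia, 17 for hepatocyte, 12 for endothelial, 18 for Hox and 60 for ribosomal protein genes. Camera adjusted p-values were 5.4e-22 for neuron, 6.3e-06 for glia, 2.85e-09 for hepatocyte, 1.03e-07 for endothelial and 6.52e-08 for Hox genes. With an estimated correlation none of the lists passed, the neuron list having adjusted p = 0.14, the glia, hepatocyte, endothelial, Hox, immediate early, heat shock and ribosomal protein lists adjusted p = 0.383 and the oxidative phosphorylation and olfactory receptor lists adjusted p = 0.398. Macrophage, lymphocyte, fibroblast and smooth muscle, adipocyte and erythroid lists did not pass camera in either form. In all, limma called 6030 of 26944 genes in brain, 2353 higher and 3677 lower. The split was near even with all libraries at the same median and spread, with 3574 higher and 3706 lower, and with a prior variance without trend, with 1267 higher and 1154 lower. Without brain Frozen the count was 2505.

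Heart stood apart through contractile genes. Of 26 cardiomyocyte markers, 25 were higher and none was lower, with the myosin heavy chain Myh6 at 3.33 ± 0.20, the transcription factor Hand2 at 3.14 ± 0.26 and the cardiac actin Actc1 at 3.08 ± 0.30. Troponin I (Tnni3) was higher by 3.10 ± 0.30, the natriuretic peptide gene Nppb by 3.15 ± 0.39 and Nppa, another natriuretic peptide gene, by 1.64 ± 0.40. Nppa stood at 5.44 (log2 CPM) in heart FFPE and 3.08 in heart Frozen. The latter lay below brain Frozen at 3.41 and above kidney and liver Frozen at 2.38 and 0.89. The largest difference was in Cox6a2, a subunit of cytochrome c oxidase found in muscle, by 3.91 ± 0.38. Endothelial genes were higher for 13 of 15 members, including Kdr by 1.93 ± 0.21, fibroblast and smooth muscle genes for 7 of 11, and immediate early genes for 12 of 20, with the transcription factor Klf4 at 2.24 ± 0.22. Oxidative phosphorylation genes were higher for 16 of 78 members, led by Cox6a2, Cox8b and Cox7a1, which encode muscle forms of their subunits. Housekeeping genes were higher for 5 of 16 members, with a median of 0.45 (log2), ribosomal protein genes had 72 of 79 and clustered histone genes 51 of 57 positive values, and olfactory receptor genes were lower for 74 of 1108 members and higher for 3. Of all 26944 genes 1970 were lower in heart, so the share of lower olfactory receptor genes was not above that of all genes. With all libraries at the same median and spread, the medians in heart went from 0.45 to 0.28 for housekeeping, 0.50 to 0.41 for oxidative phosphorylation, 0.92 to 0.57 for immediate early, -0.42 to -0.092 for olfactory receptor and 1.97 to 1.83 for cardiomyocyte genes.

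Hepatocyte genes were lower in heart for 21 of 26 measured members, with albumin (Alb) at -2.11 ± 0.27, and nephron genes for 14 of 27. The genes with the largest falls were Olfr869, Pou3f4, Rhox10, Krtap17-1 and Olfr178, whose heart libraries had between 0 and 11 counts. Adjusted over the list alone, 26 cardiomyocyte, 13 endothelial and 17 immediate early genes were higher and 23 hepatocyte genes were lower. Camera adjusted p-values were 2.17e-36 for cardiomyocyte, 9.49e-17 for endothelial, 8.56e-12 for immediate early and 7.16e-21 for hepatocyte genes. With an estimated correlation none of these lists passed, the cardiomyocyte list having adjusted p = 0.109 and the endothelial list adjusted p = 0.195. In all, limma called 4508 genes in heart, 2538 higher and 1970 lower, a majority that turned to 2053 higher and 2281 lower with all libraries at the same median and spread. The count was 872 without heart Frozen, 3000 without kidney Frozen and 1373 without a variance trend.

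Kidney had its largest differences in Hox genes. Of 39 measured, 29 were higher and none was lower, with Hoxa7 at 3.83 ± 0.25, Hoxa9 at 3.72 ± 0.25, Hoxb7 at 3.61 ± 0.27 and Hoxb8 at 3.44 ± 0.24. Of 27 nephron markers, 22 were higher, among them the phosphate transporter Slc34a1 of the proximal tubule by 2.60 ± 0.23, the transcription factor Pax8 by 2.78 ± 0.26 and Umod, which encodes uromodulin of the thick ascending limb, by 2.73 ± 0.27. Kap, an androgen-regulated kidney gene, was higher by 3.56 ± 0.48. Cardiomyocyte genes were lower for 11 of 26 members, with Gata4 at -1.61 ± 0.22, and hepatocyte genes for 10 of 26 measured. Hepatocyte medians in kidney, 4.02 in Frozen and 4.10 in FFPE (log2 CPM), lay above those in brain and heart and below those in liver. Among the largest falls, Shld1 was at -2.29 ± 0.25, Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, at -2.25 ± 0.24 and Cox6a2 at -2.01 ± 0.38, while Igkv4-60 and Traj35, also named by the rule, had 0 or 1 count in the kidney libraries.

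Adjusted over the list alone, 32 Hox and 23 nephron genes were higher in kidney and 18 cardiomyocyte genes lower. Camera adjusted p-values were 7.42e-70 for Hox and 6.96e-41 for nephron genes. With an estimated correlation the Hox list passed, with adjusted p = 0.0391, and the nephron list did not, with adjusted p = 0.0616. In all, limma called 1407 genes in kidney, 860 higher and 547 lower. The count was 265 without kidney Frozen, 403 without kidney FFPE and 130 without a variance trend, of which 115 were higher. It was 2264 after quantile normalization and 2375 with all libraries at the same median and spread.

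Liver differed most through genes of hepatocyte metabolism and secretion. All 26 measured hepatocyte markers were higher. Cyp8b1, a sterol hydroxylase of bile acid synthesis, was higher by 4.65 ± 0.29, tyrosine aminotransferase (Tat) by 4.13 ± 0.24, Alb by 3.95 ± 0.27 and the apolipoprotein gene Apoa1 by 2.76 ± 0.25. The acute phase genes Crp and Orm1 were higher by 4.31 ± 0.32 and 4.25 ± 0.32, Rdh7 by 4.21 ± 0.25 and Apon by 4.14 ± 0.28. Ribosomal protein genes were higher for 18 of 79 members. Neuron genes were lower for 15 of 25 members and cardiomyocyte genes for 17 of 26, with Myh6 at -1.63 ± 0.20, and Kcnj11, a potassium channel gene, was lower by -2.96 ± 0.25. Cardiomyocyte medians of liver, 3.86 in Frozen and 4.25 in FFPE (log2 CPM), lay above those of kidney, 3.52 and 3.91. The rule also named Trav6-5, Frg2f4, Ighv1-19-1 and Olfr1322 among the largest falls, and their liver libraries had between 0 and 4 counts.

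Adjusted over the list alone, 26 hepatocyte genes were higher in liver and 21 neuron genes lower. The camera adjusted p of the hepatocyte list was 5.73e-46. With an estimated correlation no list passed in liver, the hepatocyte list having adjusted p = 0.263. In all, limma called 5640 genes in liver, 3019 higher and 2621 lower, a majority that turned to 2758 higher and 3062 lower after quantile normalization and to 2892 and 2905 at the same median and spread. The count was 2200 without liver Frozen and 2677 without a variance trend.

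The same comparison was described within each preservation, where it has no test. Hepatocyte genes lay above the mean of the other organs by a median of 3.27 (log2) in liver Frozen and 2.52 in liver FFPE, and cardiomyocyte genes by 2.21 in heart Frozen and 1.85 in heart FFPE. Neuron genes lay above by 1.57 in both brain libraries, nephron genes by 1.46 in kidney Frozen and 1.35 in kidney FFPE, and Hox genes by 1.79 and 2.18. Genes at least 2-fold away from the mean of the other organs were fewer in FFPE for each organ. They numbered 4634 in Frozen and 2888 in FFPE for brain, 4235 and 1955 for heart, 1654 and 1327 for kidney, and 4885 and 2590 for liver. Quantile normalization within each preservation gave 4297 and 2984, 3003 and 1685, 1718 and 1327, and 3829 and 2588 in that order. The spread over genes was less alike in Frozen, with SDs of 1.84 to 2.31, than in FFPE, with 1.82 to 1.99. How far spread accounts for the lower FFPE counts was not tested. Genes that were at least 2-fold higher in both preservations numbered 964 in brain, 719 in heart, 429 in kidney and 1180 in liver, where independent lists would share 140, 79.0, 33.6 and 155. Across genes, which are not independent replicates, the organ difference in FFPE and in Frozen had a Pearson correlation of 0.60 in brain, 0.496 in heart, 0.334 in kidney and 0.545 in liver. Without the lowest 25% of genes these were 0.743, 0.731, 0.577 and 0.759. Without kidney Frozen the Frozen brain count was 7016, and without brain Frozen the Frozen kidney count was 3409.

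FFPE was compared with Frozen over the 4 organs. As the animals are not given, differences between mice are not separated from preservation in these calls. The genes with the largest rises in FFPE had almost no counts in Frozen tissue. Skint3, of a family expressed in skin and thymus, had 378 counts over the 4 FFPE libraries and 0 in Frozen, at least 30.1-fold higher against a floor of 3 counts per library. The fitted differences were 6.28 ± 0.57 (log2, SE) for Skint4 and 5.63 ± 0.65 for Skint9, which had 5 and 3 Frozen counts in total, and 6.99 ± 0.54 for BC018473. Vmn1r255, a vomeronasal pheromone receptor gene, had 0 counts in Frozen and was at least 8.23-fold higher in FFPE. Skint3 lies on chromosome 4 from 112232245 to 112300468 and Vmn1r255 on chromosome 7 from 22533964 to 22534887, in GRCm38. Lower in FFPE in all 4 organs were Cwc22, a splicing factor, by -1.95 ± 0.20 with limma adjusted p = 4.04e-08, and 4 neighbouring immunoglobulin heavy chain V segments, Ighv8-14 by -2.32 ± 0.53, Ighv8-13 by -2.18 ± 0.64, Ighv8-12 by -2.17 ± 0.57 and Ighv8-11 by -1.96 ± 0.53. Vomeronasal receptors and V segments are families of similar copies, and reads shared between copies make their single values uncertain.

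**Figure D2:**
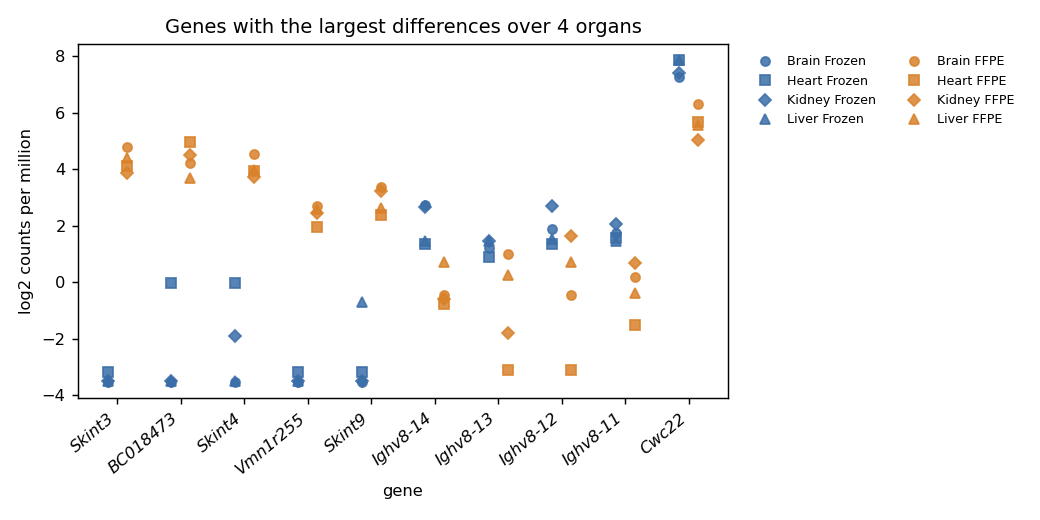
Level in log2 CPM of the 10 genes with the largest differences, with 1 point per library, blue for Frozen and orange for FFPE, and a symbol per organ. Skint3 and Vmn1r255 sit at the level of 0 counts in the 4 Frozen libraries.

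Gene lists moved in both directions. Vomeronasal receptor genes rose in FFPE for 74 of 348 members and fell for none, with Vmn1r148 at 4.78 ± 0.44 and Vmn1r132 at 3.65 ± 0.42. Oxidative phosphorylation genes fell for 18 of 78 members and rose for none, with the complex I subunits Ndufb4 at -1.23 ± 0.22, Ndufb2 at -0.98 ± 0.21 and Ndufb11 at -0.995 ± 0.22. Heat shock genes fell for 4 of 10 members, among them the chaperonin partner Hspe1 by -0.86 ± 0.20, Hsph1 by -0.81 ± 0.20 and Dnajb1 by -0.70 ± 0.19. Ribosomal protein genes fell for 3 of 79 members, Rpl19 at -0.92 ± 0.20, Rpl13 at -0.72 ± 0.21 and Rps23 at -0.70 ± 0.21. Clustered histone genes fell for 2 of 57 members, H2bc12 at -1.23 ± 0.32 and H3c6 at -0.75 ± 0.21, and rose for 1. Elavl4, which encodes a neuronal RNA-binding protein, was the 1 of 25 neuron genes that rose, by 0.91 ± 0.21. Hoxc8 was the 1 of 39 Hox genes, by 1.01 ± 0.25, although it stood at -0.078 in brain. Of all 26944 genes, 539 rose and 515 fell. The 1 to 3 calls in the ribosomal protein, clustered histone, neuron and Hox lists are too few to set these lists apart from that share. Nppa was higher by 1.18 ± 0.34 with limma adjusted p = 0.0453, while the markers Snap25, Gfap, Myh6, Umod, Slc34a1, Alb, Apoa1, Actb and Gapdh did not pass.

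Adjusted over the list alone, 87 vomeronasal receptor genes rose and 1 fell, and 36 oxidative phosphorylation, 8 heat shock and 12 ribosomal protein genes fell. Camera adjusted p-values were 1.03e-19 for vomeronasal receptor, 1.54e-21 for oxidative phosphorylation, 6.99e-08 for heat shock, 1.98e-08 for ribosomal protein, 3.54e-05 for clustered histone, 4.34e-04 for neuron and 0.00163 for Hox genes. With an estimated correlation no list passed, the lowest being adjusted p = 0.547. The other 14 lists did not pass in either form, among them olfactory receptor genes with 7 of 1108 members higher and 1 lower. In all, limma called 1054 of 26944 genes, 539 higher and 515 lower in FFPE, and 4302 had an unadjusted p under 0.05. The count and its split moved with the setting, to 174 higher and 443 lower without the lowest 25% of genes and to 328 higher and 41 lower without a variance trend. It was 1951 without brain FFPE (654 higher and 1297 lower) and 1969 without brain Frozen (682 and 1287), and between 501 (355 and 146, without liver FFPE) and 577 (410 and 167, without kidney Frozen) when any other library was left out. Once 1 library of an organ is left out, the organ term absorbs its partner. These 8 runs thus amount to 4 fits that each omit 1 organ, apart from the variance trend.

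Mitochondrial genes took a larger share of the counts in FFPE in 4 of 4 organs. The share was 36.0% in heart FFPE against 5.45% in heart Frozen, 18.4% against 4.52% in kidney, 16.04% against 5.62% in brain and 12.7% against 5.29% in liver. The means were 20.8% ± 10.4 (SD, n = 4) and 5.22% ± 0.484, with an exact sign-flip permutation p of 0.125, two-sided, the smallest that 4 pairs allow. Each share has a counting interval of less than 0.1 percentage points on either side. The mean rise over the 4 organs was 2.95 (log2) for ND2 and 1.11 for COX3, the largest and the smallest of the 15 mitochondrial genes.

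Within an organ, FFPE and Frozen differed more in heart and liver than in brain and kidney in these libraries, a difference that was not tested. At least 2-fold differences were found for 3040 genes in liver, 1990 in heart, 1234 in kidney and 1038 in brain, where counting error alone would give 44.4, 41.6, 41.5 and 44.9. Without the lowest 25% of genes they numbered 2352, 1586, 595 and 420, and after quantile normalization 2052, 1461, 1226 and 987, which brings heart nearer to kidney. The median of housekeeping genes lay above that of olfactory receptor genes, which are silent in these organs, by 4.56 (log2) in heart Frozen and 3.74 in heart FFPE, and by 4.40 in liver Frozen and 3.45 in liver FFPE. In brain and kidney the gap was larger in FFPE, 3.03 against 2.67 and 3.53 against 3.09. The fall in heart and liver depends on the scaling, as the FFPE minus Frozen gap was -0.82 and -0.94 in the deposited values, -0.037 and -0.12 after quantile normalization, which makes the distributions of all libraries equal, and 0.082 and 0.050 at the same median and spread. Over the 4 organs the gap did not pass an exact sign-flip permutation test, with p = 0.5, two-sided, where 0.125 is the smallest possible. The gap between ribosomal protein and vomeronasal receptor medians, which was not tested, was smaller in FFPE than in Frozen in all 4 organs. It was 1.46 against 1.78 in brain, 2.33 against 2.53 in kidney, 2.44 against 3.59 in heart and 2.09 against 3.62 in liver. This vomeronasal list includes 85 genes of a chromosome 7 block with a median FFPE minus Frozen of 3.14, against 0.27 in the other 263. In brain the ribosomal protein median went from 4.27 in Frozen to 4.34 in FFPE, and the vomeronasal median from 2.49 to 2.88. The smaller gap there is thus no fall of active genes, and no gap was computed without the block.

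**Figure D3:**
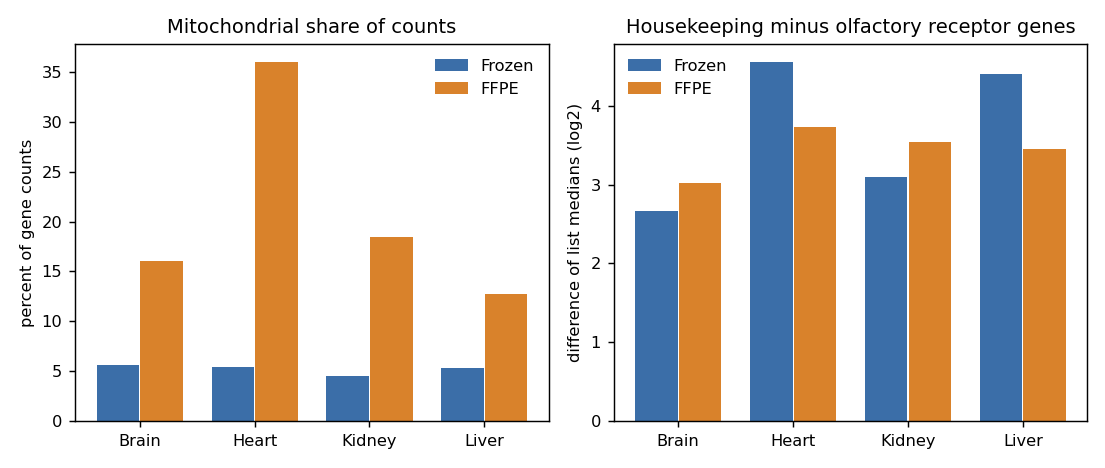
Left, mitochondrial genes as a percent of all gene counts in each library, and right, the difference of the medians of housekeeping and olfactory receptor genes in log2 units, with blue bars for Frozen and orange bars for FFPE and 1 library per bar. The mitochondrial share is 36.0% in heart FFPE, and the gap falls from 4.40 to 3.45 in liver.

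Single lists within an organ were described by their medians. Oxidative phosphorylation genes were lower in FFPE by a median of -0.84 (log2) in liver, -0.69 in heart and -0.49 in kidney, and stood at -0.039 in brain. Heat shock genes stood at -1.22 in heart, -0.92 in liver, -0.31 in kidney and -0.027 in brain, and shrank to -0.82 in heart and -0.44 in liver after quantile normalization and to -0.62 and -0.46 with all libraries at the same median and spread. Hepatocyte genes stood at -0.57 in liver FFPE relative to Frozen, with Apoa1 at a ratio of 0.442 (95% counting interval 0.397 to 0.492) and Alb at 0.947 (0.865 to 1.04). Cardiomyocyte genes stood at -0.31 in heart, although Myh6 had a ratio of 1.07 (1.01 to 1.14) and Nppa, with 187 FFPE counts and 38 Frozen counts, a ratio of 5.21 (3.66 to 7.60). Nephron genes stood at 0.059 in kidney and neuron genes at 0.39 in brain, where Snap25 had a ratio of 1.92 (1.62 to 2.27). Neuron genes also stood at 0.37 in liver and 0.25 in heart, and at -0.094 in kidney, so their rise was not particular to brain. After quantile normalization the hepatocyte median in liver was -0.074 and the cardiomyocyte median in heart -0.0025, and with all libraries at the same median and spread the latter turned to 0.15.

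**Figure D4:**
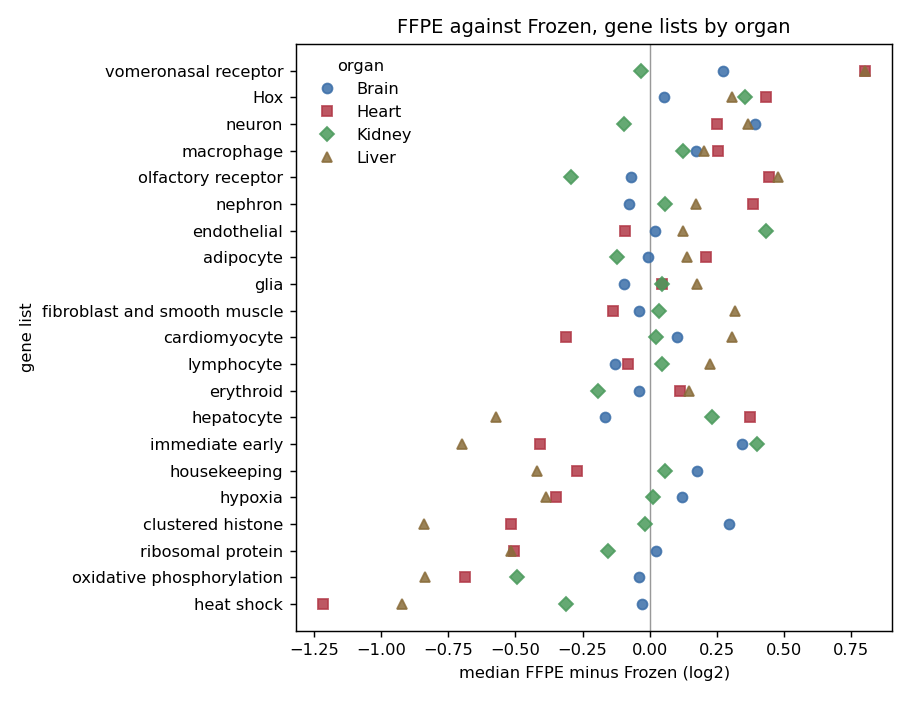
Median FFPE minus Frozen difference of each of the 21 gene lists, in log2 units on the horizontal axis, with 1 symbol per organ and 1 pair of libraries behind each. Heat shock genes stand at -1.22 in heart and -0.027 in brain.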

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

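The tests of explanations in this part were chosen after the results had been seen, except the thinning of libraries to equal depth. In 73 groups of 4 values, 6 had a value far from the other 3 by Dixon's ratio, and chance alone gives about 1 in 20.

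Among FFPE libraries the scaling factor of heart was 0.749, and among Frozen libraries the total of liver was 6164562 counts. Over the 4 organs, the FFPE minus Frozen difference of Cwc22 was -0.93 (log2) in brain and as low as -2.36 in the others. The brain difference stood apart for Hoxc8 at -0.078 and Snap25 at 0.94, and the kidney difference stood apart for Myh6 at -0.32. Of 21 lists, 3 had medians in opposite tails of random lists in a pair of organs, differences that were not tested. The hepatocyte median in heart lay above that in liver by 0.94, which shrank to 0.22 after quantile normalization and 0.28 at the same median and spread. The immediate early median in kidney lay above that in liver by 1.10, against 0.70 and 0.58 under these scalings. The clustered histone median in brain lay above that in heart by 0.81, against 0.70 and 0.75.

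Genes at least 2-fold higher in FFPE past the limma threshold numbered 475, and 6 of them had 0 counts in all Frozen libraries. Of the 349 placed on nuclear chromosomes, 66.5% had another such gene within 200 kb, against 24.1% in the median and 34.7% in the highest of 1000 random sets matched on level, 84 lay on chromosome 7 between 19 and 24 Mb and 38 on chromosome Y, where 109 genes were tested. Among the 227 outside both, 60.4% had such a neighbour, against at most 23.8% in random sets. On chromosome Y, Sry stood at -1.45 ± 0.43 (log2, SE) with limma adjusted p = 0.0506, and Uty at -0.25 ± 0.19, Usp9y at 0.18 ± 0.22, Eif2s3y at -0.097 ± 0.24, Kdm5d at 0.047 ± 0.19 and Ddx3y at -0.016 ± 0.20 did not pass. Xist on chromosome X was at 0.39 ± 0.19 with adjusted p = 0.312. These genes, all with counts in every library, were chosen after values had been seen. This grouping would follow from inherited sequence differences between the mice used for FFPE and for Frozen tissue, as a hypothesis. A difference in copy number between these mice, as may apply on chromosome Y, would be a form of it. Gene families that share reads between copies stay open too, because the labels give no strain and families lie together in the genome. The 103 genes at least 2-fold lower in FFPE were not tested for such grouping. The tables argue against more background fragments in FFPE as the source of the chromosome 7 block. The 263 vomeronasal receptor genes outside it had a median of 0.27 (95% bootstrap interval 0.19 to 0.31) and the 85 in it 3.14. These are medians of mean differences over the 4 organs, and the interval resamples genes of the same 8 libraries. The block was set after the results had been seen, which favours a higher value inside it. As to the count of 1054 called genes, 3 of the 32 splits that could be fitted, the real one included, gave as many, and the highest other split gave 1821. With an organ term, a split that leaves 2 organs whole is the same fit as its mirror, with the sides of the parted organs exchanged. Both other splits are such a pair and thus 1 fit. That fit is the real preservation contrast of heart and liver, with brain and kidney whole, so it is no unrelated grouping. The 3 of 32 is therefore no valid share, and chance is not excluded. The other 7 splits that part all 4 organs gave 0 by limma, with 293 to 2930 genes at an unadjusted p under 0.05, and these 8 splits are too few for a share under 0.05.

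The mitochondrial share was higher in FFPE. Mitochondrial counts were higher in every organ, with the lowest FFPE to Frozen ratio at 1.72 in liver and the highest at 7.89 in heart, while nuclear counts had ratios of 0.658 to 0.938. Sequencing sets the total of a library, so these ratios do not separate a loss of nuclear fragments from a gain of mitochondrial ones, and both stay open. Whether mitochondrial DNA is held back or released differently by the extractions, and whether organ content of mitochondria adds to it, was not tested.

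The gap between housekeeping and olfactory receptor genes was smaller in FFPE heart and liver, by -0.82 and -0.94 (log2) in the deposited values, by -0.037 and -0.12 after quantile normalization, and it was larger by 0.082 and 0.050 at the same median and spread. The fall goes with the spread of the 26944 tested genes, an SD of 1.99 in heart FFPE against 2.31 in Frozen and of 1.95 against 2.30 in liver. In both organs own-organ markers stood lower and markers of the other 3 organs higher, by a difference of -0.57 in heart and -0.82 in liver, which restates the gap and decides nothing about background, so that stays open without an input. With both libraries thinned to equal nuclear counts the gap difference was -0.72 in heart and -0.86 in liver, a largest shift of 0.104 that just passed the limit of 0.1 set beforehand, so a part played by depth stays open. Resident endothelial, macrophage and connective tissue markers stood below other-organ markers by -0.34 in heart (95% bootstrap interval over genes in 1 pair of libraries -0.51 to -0.027), but by -0.064 (-0.21 to 0.16) after quantile normalization. In liver the value was -0.090 (-0.25 to 0.082), so fewer cardiomyocytes or hepatocytes stay open.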

How the results depend on the processing

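The comparisons of each organ over both preservations, the setting of all libraries to the same median and spread, and the analysis without mitochondrial genes were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate number to block on and each group has 1 column, while the organ term compares FFPE with Frozen within organs. Also not run were fits within 1 organ or 1 preservation, subtraction of the input, another pseudocount (the values are on a log scale), the no-trend fit for results without a test, and results against input, as no input column was analysed here.

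Without a variance trend the called genes were 369 for FFPE against Frozen, 2421 for brain, 1373 for heart, 130 for kidney and 2677 for liver, all over 1.5 times lower than the main counts, and the cause was not tested. Without the lowest 25% of genes, FFPE against Frozen gave 617, with fewer genes tested. By 2-fold counts, brain FFPE against Frozen gave 420 and kidney 595, and the correlations of Frozen and FFPE organ differences were 0.743 for brain, 0.731 for heart, 0.577 for kidney and 0.759 for liver. Kidney against other organs gave 2264 after quantile normalization and 2375 at the same median and spread, and the cause was not tested. For FFPE against Frozen, quantile normalization gave 945 genes, the same median and spread 1005 and no mitochondrial genes 1039.

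With each library left out in turn, counts ran from 501 to 1969 for FFPE against Frozen, 2505 to 7242 for brain, 872 to 5251 for heart, 265 to 1843 for kidney and 2200 to 6005 for liver. Within Frozen, 2-fold counts ran from 3844 to 7016 for brain, 4035 to 5597 for heart, 1837 to 3409 for kidney and 4248 to 6455 for liver. Within FFPE they ran from 2947 to 3412, 2099 to 2564, 1542 to 1923 and 2635 to 3260 in that order. Here leaving out a library sets the organ against a mean of fewer organs, which is a different contrast. The main FFPE counts of 2888, 1955, 1327 and 2590 and the Frozen kidney count of 1654 all lay below their ranges. The correlations ran from 0.542 to 0.591 for brain, 0.444 to 0.501 for heart, 0.232 to 0.36 for kidney and 0.463 to 0.552 for liver. Where an arm keeps 1 library, that library is assumed to vary like the others. For FFPE against Frozen, leaving out either library of an organ removes that organ from the comparison, so the 8 runs are no separate checks of single libraries. All 4 FFPE libraries stayed closest to their own organ after quantile normalization and after the removal of low genes. Leaving out 1 library could not change this for the 3 FFPE libraries whose own Frozen library remained, so it was no check. With 3 residual degrees of freedom, 18 of 100 simulated changes of 1 (log2) were called for FFPE against Frozen, among genes above a minimum mean level. The median gene had 87 to 119 counts per library, and no rate was simulated for that depth alone.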

Other observations

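Lists of other cells and states were described within single organs, where their values have no test. Over the 4 organs camera passed for clustered histone genes, though not with an estimated correlation (adjusted p = 0.757), and not for macrophage, endothelial, lymphocyte or immediate early genes. Macrophage genes stood higher in FFPE by a median of 0.17 (log2) in brain, 0.25 in heart, 0.12 in kidney and 0.20 in liver. Endothelial genes stood at 0.43 in kidney, 0.12 in liver, 0.021 in brain and -0.092 in heart, the last turning to 0.23 after quantile normalization, with liver then at 0.25. Lymphocyte genes stood between -0.13 in brain and 0.23 in liver, the latter shrinking to 0.069 after quantile normalization. Immediate early genes, which respond within minutes to stimulation, stood at 0.34 in brain, 0.40 in kidney, -0.41 in heart and -0.70 in liver, and with all libraries at the same median and spread the heart value turned to 0.26 and the liver value shrank to -0.19. After quantile normalization they were -0.084 and -0.30. Clustered histone genes stood at 0.30 in brain, -0.018 in kidney, -0.52 in heart and -0.84 in liver, with the same signs under both other scalings. Glia, nephron, adipocyte, erythroid, fibroblast and smooth muscle, and hypoxia lists did not pass camera for FFPE against Frozen over the 4 organs.

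The Skint genes form a cluster on chromosome 4, and its members differed between preservations to unequal degrees. Over 4 libraries each, Skint3 had 378 FFPE and 0 Frozen counts, Skint4 317 and 5, and Skint9 148 and 3, while Skint7 had 243 and 260, Skint8 126 and 123, and Skint10 160 and 142. Between these lay Skint6 with 528 and 136 counts and Skint5 with 633 and 338, which passed the limma threshold, and Skint11 with 173 and 94, Skint2 with 184 and 136 and Skint1 with 127 and 86, which did not, as Skint7, Skint8 and Skint10 did not. All but Skint3, Skint4 and Skint9 were chosen after their values had been seen. These 3 genes, with 0 to 5 Frozen counts, are neighbours in GRCm38, from 112072016 to 112433985. They lie between Skint1, which starts at 112006269, and Skint2, which starts at 112613598. The inherited sequence difference raised above as a hypothesis stays open for this stretch and was not tested there.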
